A study of Mus musculus with 6 samples.

How the data were processed

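Bulk RNA was measured in epididymal white adipose tissue of Eepd1 knockout (EKO) and wild-type (WT) C57BL/6J mice after 3 months of high-fat diet, with 3 libraries per genotype. Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with an mRNA-seq kit for Illumina sequencing. The genome build was GRCm38, per the submitters' processing notes; the aligner, the counting tool and its strand setting are not given in the sources used here. Without strand information, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies, such as the haemoglobin genes and the mast cell tryptases, are reported as uncertain. Samples were grouped by the genotype in the labels, and replicate numbers are those of the labels.

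The authors deposited 1 table of 32244 genes with raw read counts for each of the 6 libraries, per the file headers. Every row analysed had an Ensembl gene identifier and at least 1 count. The same table holds, per the file headers, a mean signal per gene over the 6 libraries, a fold change (ratio of EKO to WT), its log2 value, a p-value and an adjusted p-value, all computed by the authors. The deposited mean signal equals the mean of counts divided by median-of-ratios size factors, with a median relative difference of 2.79e-06. The deposited log2 fold changes differ from a DESeq2 Wald fit of the deposited counts by a median of 1.61e-05, and that fit with the same thresholds gave the same 1637 genes. The header names no tool for them. Gene symbols, coordinates, biotypes and gene ontology terms come from the same table.

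Total counts per library were 17400289, 17229585 and 17215072 in EKO replicates 1, 2 and 3 and 17400290, 18264684 and 18330206 in WT replicates 1, 2 and 3. The most abundant gene took between 1.08% and 2.66% of the counts of a library. Every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom of at least 14.7), so each library was counted once.

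The main test was the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with default settings after filterByExpr and TMM scaling, with genotype as the sole term, all 6 libraries and a Benjamini-Hochberg adjusted p under 0.05. It tested 16121 genes. Standard errors are the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM (counts scaled to a common library total), with the SD over 3 libraries. For 51 fixed gene lists (1066 genes, 1042 found in the table), limma's camera (limma 3.58.1) was run on voom values with a preset inter-gene correlation of 0.01, over the 50 lists with at least 5 tested genes. List members were also adjusted over the list alone. Gene ontology terms of 10 to 500 genes were tested with camera and, for the genes the authors' deposited table calls, with a one-sided hypergeometric test against the 16154 genes with a deposited adjusted p. Both term tests were chosen after the edgeR test had called no gene, since the enrichment planned on edgeR calls then had no genes.

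The gene lists, the tests and a rule for the genes named were fixed before the data were examined. The rule takes Eepd1; up to 10 genes each way with the largest change among those past the threshold with non-overlapping groups and at least 1 CPM; the 4 tested members of each list with the smallest p; and 12 genes of fat and macrophage biology. The second part named 0 genes, and the rule named 201 in all, of which the text uses a part. The second part applied to the genes called in the authors' deposited table was added after the data were seen.

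The fits were tested on simulated counts with the means, library sizes and dispersions of this comparison and 200 changed genes. With 15844 genes tested, edgeR recovered 8% of genes changed 2-fold and 44% of those changed 4-fold, with 5 false among 57 calls. DESeq2, over 16121 genes, recovered 41% and 80%, with 72 false among 193 calls, and limma-voom 5% and 42%, with 4 false among 51. The recovered and false shares hold for 200 changed genes and could differ if more genes changed. Camera called 5 of 5 shifted lists and 0 of 5 unshifted lists. These were random lists of genes simulated independently of one another. The check therefore cannot show how camera behaves at the preset correlation when genes are correlated.

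Alternatives were other scalings (DESeq2 size factors, library totals, upper quartile), other count filters, DESeq2 1.42.0, and limma-voom with and without sample quality weights. Others were the replicate number as a block, each library left out in turn and other thresholds. For lists they were an estimated correlation, fry and removal of members shared with another list, the last from the cell type marker lists alone. Added after the data were seen were an adjusted p of 0.10, the newer edgeR dispersion fit and robust edgeR. Alternatives planned for normalized values were not needed, because the table holds counts.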

Results

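Epididymal white adipose tissue, the visceral fat pad beside the epididymis of male mice, was profiled by bulk mRNA sequencing in Eepd1 knockout mice (EKO) and in wild-type mice (WT) on the C57BL/6J background. All mice had been fed a high-fat diet for 3 months. There were 3 libraries per genotype and 1 comparison, EKO against WT. The series title places it in the study of lipolysis, thermogenesis and protein kinase A signalling in obesity. Total counts ranged from 17215072 to 18330206 per library, and 16121 of 32244 listed genes had enough counts to be tested. A gene with no count in a library is limited to below 0.154 to 0.192 CPM (counts scaled to a common library total with TMM factors), the level of 3 counts, and this limit covers counting error only. The labels do not say whether replicates of a genotype came from separate animals, so p-values measure the spread between these samples.

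Eepd1, the targeted gene (ENSMUSG00000036611, protein coding, chromosome 9, 25481547 to 25604110, plus strand, GRCm38), was lower in every EKO library than in every WT library. It stood at 152, 47.7 and 116 CPM in EKO replicates 1, 2 and 3 and at 244, 304 and 192 CPM in WT replicates 1, 2 and 3. The means were 105 ± 52.9 and 247 ± 56.1 CPM (SD, n = 3 per group), a log2 difference of -1.23 ± 0.42 (SE). The edgeR quasi-likelihood adjusted p was 0.106, while the DESeq2 Wald test gave an adjusted p of 0.0162, within a range of 0.0162 to 0.255 over all alternatives. The counts cover the whole gene, and the part deleted in the knockout is not given in the sources used here, so reads from outside that part cannot check the genotype.

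By the medians of fixed gene lists, EKO fat held fewer adipocyte transcripts and more macrophage, lysosome and matrix transcripts than WT fat. Camera called these lists at the preset inter-gene correlation, and no list with an estimated correlation. The rotation test fry did not call them (adjusted p = 0.117 for the adipocyte identity, macrophage and lysosome lists, 0.168 for the matrix list). Of the 16121 genes tested, 6904 (42.8%) had all 3 EKO libraries on one side of all 3 WT libraries, where chance gives 10%. Of these, 4050 were higher and 2854 lower in EKO. Genes that vary together separate together, so 42.8% set against 10% is not a test of the genotypes. The spread between libraries of a genotype was wide, with a biological coefficient of variation of 37.0%, and no gene passed an adjusted p of 0.05 in the edgeR quasi-likelihood test. The lowest edgeR adjusted p was 0.0628, and 5264 genes had an unadjusted p under 0.05, of which 3045 were higher and 2219 lower in EKO. On the same counts, limma-voom called 0 genes, limma-voom with sample quality weights 4101 and DESeq2 3392. Without WT replicate 2, edgeR called 443 genes, 323 higher and 120 lower, and 432 of the 443 were also called by DESeq2 on all 6 libraries. For this reason single genes below are described by their values, and groups by tests over fixed lists. Counts of members passing over a list alone were not set against arbitrary lists of the same size. With 5264 of 16121 genes at an unadjusted p under 0.05, such counts do not show a change particular to a list.

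The libraries of each genotype lay far apart from one another. Principal component 1 held 59.4% of the variance, with EKO replicate 2 at -87.5 and WT replicate 2 at 118 as its extremes. WT replicate 2 also held testis transcripts: Prm1, a sperm protamine, reached 412 CPM there against 14.5 in EKO replicate 3, 5.20 in WT replicate 1 and at most 0.462 in the other 3 libraries. Mitochondrially encoded transcripts made up 4.34% of the counts in WT replicate 2, 3.08% and 2.51% in WT replicates 1 and 3, and 1.77 to 2.41% in the EKO libraries. Hepatocyte markers (12 tested genes) also differed within each genotype, by list median of log2 CPM relative to the mean of the 6 libraries. The medians were -1.86, -2.80 and 3.32 in EKO replicates 1, 2 and 3 and 2.11, -2.11 and 1.21 in WT replicates 1, 2 and 3.

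**Figure D1:**
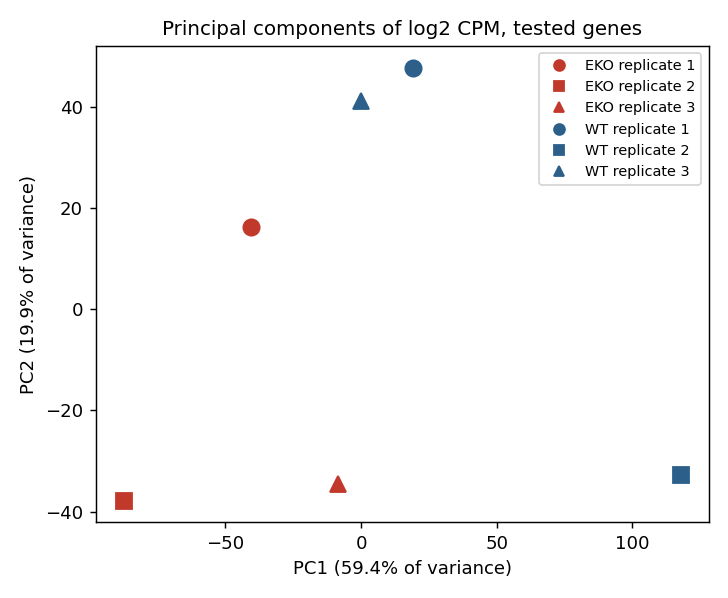
Principal components 1 (x axis, 59.4% of variance) and 2 (y axis, 19.9%) of log2 CPM over the tested genes, with 1 point per library coloured by genotype. WT replicate 2 lies at 118 on component 1, apart from WT replicates 1 and 3 at 19.1 and -0.15.

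Adipocyte genes were lower in EKO as a group. Adiponectin (Adipoq), the main secreted protein of fat cells, averaged 457 ± 266 CPM in EKO and 2028 ± 625 in WT (SD, n = 3), a 4.44-fold difference. Pck1, the glyceroneogenesis enzyme, was 6.64-fold lower (log2 -2.73 ± 0.50 SE), and Cebpa, a master regulator of adipocyte differentiation, was 1.84-fold lower. Leptin (Lep) differed less, at 1423 ± 673 CPM in EKO and 2193 ± 360 in WT, and its groups overlapped. The fatty acid transporter Cd36, which macrophages also express, stood higher in EKO at 7815 ± 1231 against 5225 ± 458 CPM. Of the 29 tested members of the adipocyte identity list, 26 were lower, with a median log2 difference of -1.40. The p of 25 of them passed when adjusted over the list alone, against 0 over all genes tested, and the authors' deposited table marks 22 as significantly down. The camera test set this list below all other genes (adjusted p = 6.64e-10 at the preset correlation, adjusted p = 0.589 with an estimated correlation).

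Genes of the lipolytic machinery were lower in EKO along with the adipocyte list. Adrb3 (chromosome 8, 27225776 to 27250616), the β3-adrenergic receptor through which catecholamines start lipolysis, averaged 28.0 ± 27.3 CPM in EKO and 289 ± 110 in WT, a 10.3-fold difference that was 23.5-fold without EKO replicate 1. The 2 lipases that release fatty acids in sequence were also lower, Pnpla2 2.47-fold (758 ± 292 against 1869 ± 374 CPM) and Lipe 3.14-fold (310 ± 149 against 974 ± 166 CPM). So were the droplet coat gene Plin1 (3.25-fold) and genes that restrain lipolysis: G0s2, the inhibitor of the Pnpla2 lipase, was 3.24-fold lower and the lactate receptor Hcar1 4.66-fold lower. Plin3, a droplet coat protein found in most cells, was 1.74-fold higher (141 ± 14.4 against 81.1 ± 6.49 CPM). Of 30 tested lipolysis genes 25 were lower, at a median log2 of -1.30, and 21 lower and 3 higher members passed when adjusted over the list alone, with 0 over all genes. The camera adjusted p was 2.48e-07 at the preset correlation, with adjusted p = 0.589 with an estimated correlation.

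**Figure D2:**
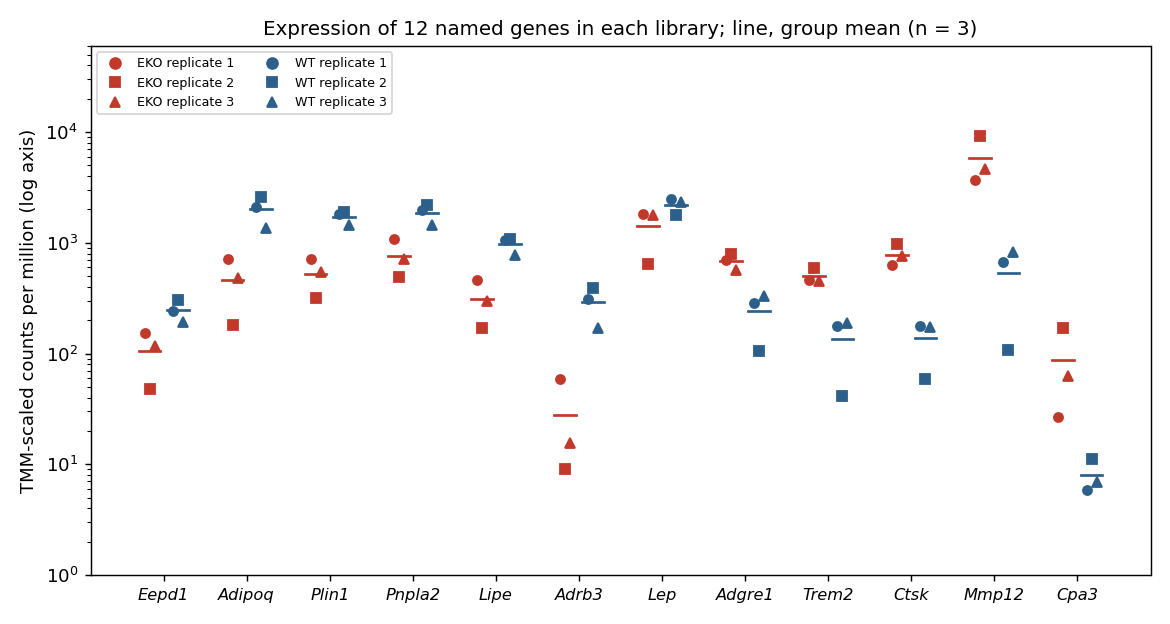
TMM-scaled CPM on a log axis (y) of 12 named genes (x) in each of the 6 libraries, with the mean of each genotype (n = 3) as a line. Adipoq, Plin1, Pnpla2, Lipe and Adrb3 lie lower in all 3 EKO libraries, Adgre1, Trem2, Ctsk, Mmp12 and Cpa3 lie higher, and Lep overlaps.

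Protein kinase A and cAMP signalling genes moved in both directions and did not shift as a list. Adenylyl cyclase Adcy6 was 2.06-fold lower (89.7 ± 16.1 against 185 ± 13.0 CPM), while another cyclase, Adcy3, was 2.38-fold higher and the cAMP phosphodiesterase Pde8b 3.12-fold higher. The kinase anchor Akap10 was 1.44-fold higher. Of 43 tested members 20 were higher and 23 lower, with a median log2 of -0.07 and a camera adjusted p of 0.596. When adjusted over the list alone, 9 higher and 10 lower members passed, against 0 over all genes tested. Targets of the cAMP-responsive factor CREB included the insulin receptor substrate Irs2, 2.15-fold lower, and Rgs2, 2.60-fold higher. That list of 17 had a median log2 of -0.40 and was not called (camera adjusted p = 0.187); 2 higher and 4 lower members passed when adjusted over the list alone, against 0 over all genes.

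Some genes of thermogenic fat had few counts in this tissue. Ucp1, the uncoupling protein of brown and beige adipocytes, had 2, 4 and 7 counts in the EKO libraries and 10, 11 and 8 in the WT libraries and was too low to test. Ppargc1a, a driver of mitochondrial biogenesis, stood at 3.43 ± 1.71 CPM in EKO and 5.89 ± 2.33 in WT with overlapping groups. Ppara was 3.40-fold lower (2.00 ± 0.705 against 6.81 ± 2.35 CPM) and Adrb1, the β1-adrenergic receptor, 4.76-fold lower. Of 33 tested members of the thermogenic and beige list 21 were lower, at a median log2 of -0.41, and 5 lower and 3 higher members passed when adjusted over the list alone, with 0 over all genes. Its camera adjusted p was 0.0270 at the preset correlation and adjusted p = 0.589 with an estimated correlation. The call ended with library totals alone (adjusted p = 0.0667), upper-quartile factors (0.0625), DESeq2 statistics (0.0546), without EKO replicate 2 (0.239) and without WT replicate 1 (0.0654), within a range of 0.0160 to 0.589 over all alternatives. In the list for creatine and calcium cycling, the creatine kinase Ckb was 4.66-fold higher (703 ± 98.1 against 151 ± 73.6 CPM) and the creatine transporter Slc6a8 3.53-fold higher, while Slc25a25 was 2.43-fold lower. Over its 11 members, 2 higher and 2 lower passed when adjusted over the list alone, against 0 over all genes, and the list was not called (camera adjusted p = 0.638).

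Lipid synthesis and fuel oxidation genes were lower in EKO. The medians of these 7 lists, -0.22 to -1.05, were smaller in size than the adipocyte identity median of -1.40. Whether they changed apart from the lower adipocyte transcripts was not tested. Dgat1, which makes triglyceride from diacylglycerol, was 2.56-fold lower (70.0 ± 19.5 against 179 ± 22.5 CPM), and the lipogenic regulator Srebf1 was 1.78-fold lower. Fatty acid synthase (Fasn) averaged 442 ± 287 CPM in EKO and 1018 ± 480 in WT, with overlapping groups (2.30-fold lower, and 3.62-fold without EKO replicate 1). The fatty acid oxidation genes Eci1 and Ehhadh were 2.49-fold and 3.10-fold lower, and the branched-chain amino acid enzymes Hibch and Dbt 3.05-fold and 2.35-fold lower. All 22 tested branched-chain genes were lower, at a median log2 of -1.05, as were 26 of 29 fatty acid oxidation genes (-0.62), 26 of 30 genes of lipogenesis and triglyceride synthesis (-0.92) and all 23 genes of the tricarboxylic acid cycle (-0.41). The respiratory chain lists were lower too, 78 nuclear-encoded genes at a median of -0.22 (68 lower) and 12 mitochondrially encoded transcripts at -0.60 (all lower). The lower insulin signalling list (median log2 -0.59, 15 of 22 lower) included Irs1, 2.79-fold lower (log2 -1.48 ± 0.21 SE), and Akt2, 1.80-fold lower. Adjusted over the list alone, 17 branched-chain, 17 fatty acid oxidation, 11 lipogenesis, 12 insulin signalling and 0 genes of the tricarboxylic acid cycle passed as lower, as did 0 of either respiratory chain list, while 4 insulin signalling genes and 1 fatty acid oxidation gene passed as higher; over all genes tested 0 passed. Camera called all 7 lists at the preset correlation, with adjusted p from 3.25e-08 for branched-chain genes to 0.00598 for mitochondrially encoded transcripts, and each had adjusted p = 0.589 with an estimated correlation.

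Macrophage genes were higher in EKO, including those of lipid-laden macrophages. Adgre1, which encodes the pan-macrophage antigen F4/80, averaged 688 ± 110 CPM in EKO and 240 ± 119 in WT, a 2.86-fold difference. Trem2, the lipid-sensing receptor of lipid-associated macrophages, was 3.73-fold higher (503 ± 76.8 against 135 ± 81.4 CPM), the lysosomal protease Ctsk 5.71-fold and the tetraspanin Cd9 3.29-fold. Macrophage elastase Mmp12 reached 5866 ± 2953 CPM against 534 ± 376. All 16 tested lipid-associated macrophage genes were higher (median log2 1.90), and 17 of 18 general macrophage genes (1.29). Adjusted over the list alone, 15 and 17 of them passed as higher, against 0 over all genes. Macrophage transcripts were lowest in WT replicate 2, at a list median of -1.50 relative to the mean of the 6 libraries, against -0.41 and -0.23 in WT replicates 1 and 3. Without that library the medians were 1.45 and 1.01, and edgeR called 11 and 5 members over all genes. The camera adjusted p was 1.86e-07 and 1.98e-06 at the preset correlation, and adjusted p = 0.589 with an estimated correlation for both lists.

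Lysosome, matrix, mast cell and growth-related lists were higher as well. The lysosomal proton pump subunit Atp6v1a was 2.98-fold higher (805 ± 136 against 270 ± 84.9 CPM), within an autophagy and lysosome list in which 30 of 33 genes were higher (median log2 1.00). Cpa3 and Tpsb2, proteases of mast cell granules, were 10.8-fold and 9.82-fold higher with wide spread (86.9 ± 75.0 against 8.01 ± 2.84 CPM for Cpa3) and 5.61-fold and 5.27-fold higher without EKO replicate 2, Tpsb2 being uncertain because of near-identical copies, and all 10 mast cell markers were higher (median 3.19). Lumican (Lum), a collagen-binding proteoglycan, was 2.14-fold higher and the collagen crosslinker Loxl2 2.57-fold, among 32 of 38 matrix genes (median 0.61, and 0.40 without WT replicate 2). Ribosomal protein genes were higher in 51 of 52 cases by a median log2 of 0.34, proliferation genes in 26 of 30 (0.48, and 0.21 without WT replicate 1, for example Pcna at 2.24-fold) and endoplasmic reticulum stress genes in 16 of 22 (0.37, and 0.24 without WT replicate 2, for example Sdf2l1 at 2.29-fold). Adjusted over the list alone, 24 lysosome, 10 mast cell, 12 matrix, 9 stress, 0 ribosomal and 0 proliferation genes passed as higher and 1 stress gene as lower, against 0 over all genes tested. Camera called each list at the preset correlation, with adjusted p from 3.25e-08 for lysosome to 0.00957 for endoplasmic reticulum stress, and each had adjusted p = 0.589 with an estimated correlation.

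Vessel and red cell transcripts were lower in EKO, and mesothelial ones with overlap between the genotypes. The endothelial genes Emcn (20.6 ± 2.19 against 37.0 ± 3.09 CPM), Kdr and Pecam1 were 1.79-fold, 1.98-fold and 1.80-fold lower, and all 15 tested endothelial markers were lower (median log2 -0.95). Smooth muscle and pericyte markers were lower in 11 of 13 cases (-0.95, for example Myh11 at 2.34-fold), angiogenesis genes in 19 of 22 (-0.81, for example Vegfb at 2.41-fold) and mesothelial markers in 15 of 15 by their means (-1.34, and -2.32 without EKO replicate 3). Of those 15 mesothelial markers 1 had non-overlapping groups, where chance gives 10%. All 7 red cell transcripts were lower (median -2.48), among them Alas2, the first enzyme of erythroid haem synthesis, at 8.33 ± 2.54 against 46.5 ± 13.6 CPM. Adjusted over the list alone, 13 endothelial, 10 angiogenesis, 7 red cell, 0 smooth muscle and 0 mesothelial genes passed as lower and 2 angiogenesis genes as higher, against 0 over all genes. Camera called all 5 lists at the preset correlation, with adjusted p from 9.11e-08 for endothelial to 0.00325 for smooth muscle, and each had adjusted p = 0.589 with an estimated correlation. The mesothelial call ended with sample quality weights (adjusted p = 0.152, range 9.67e-07 to 0.589 over all alternatives).

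**Figure D3:**
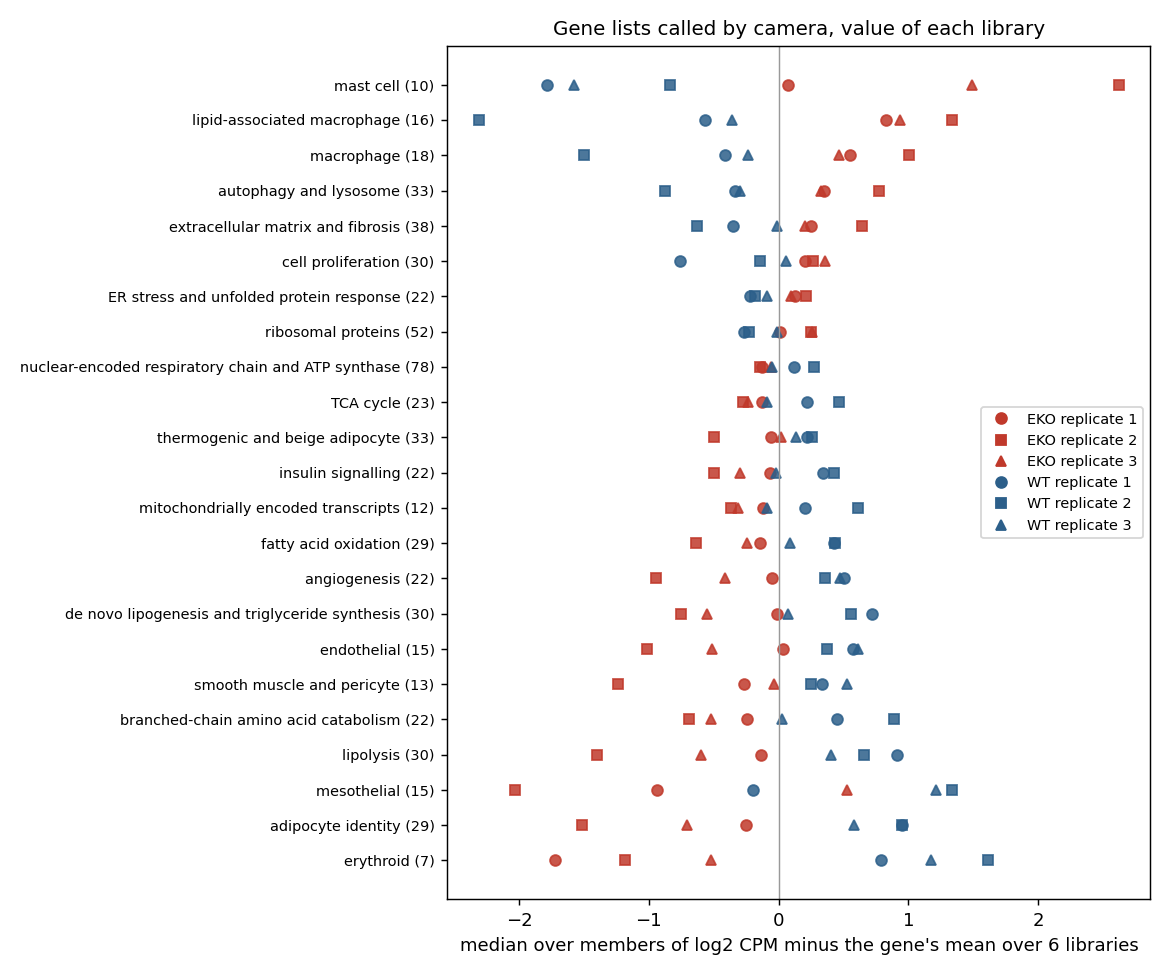
For each of the 23 lists called by camera at the preset correlation (y axis, number of tested genes in brackets), the median over members of log2 CPM minus the gene's mean over 6 libraries (x axis), with 1 point per library. EKO libraries lie above WT libraries in the 8 higher lists and below them in the 15 lower lists except the mesothelial one, and each list had adjusted p = 0.589 with an estimated correlation.

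Of 50 tested lists, camera called 23 at the preset correlation and did not call 27. It called 0 with an estimated correlation, and the rotation test fry called 4. Among the uncalled immune lists were pro-inflammatory cytokines (camera adjusted p = 0.247), interferon response (0.237), complement (0.596), alternative macrophage activation (0.963), class II antigen presentation (0.700), monocytes and dendritic cells (0.910), neutrophils (0.957), T and NK cells (0.895) and B and plasma cells (0.677). Metabolic and stress lists without a call were cholesterol synthesis (0.346), cholesterol efflux (0.895), glycolysis (0.400), hypoxia (0.313), circadian clock (0.237), antioxidant response (0.596), DNA damage response (0.377) and handling stress (0.658). The other uncalled lists were preadipocytes and fibroblasts (0.809), lymphatic endothelium (0.0722), skeletal muscle (0.105), epididymis and testis (0.281), hepatocytes (0.247), Schwann cells (0.638) and the haemoglobin and platelet list (0.700). For complement, alternative macrophage activation, class II antigen presentation, neutrophils and hepatocytes, the median, mean and test did not all share a sign. The pancreas list had 1 tested gene and was not tested.

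The authors' deposited table marks 1637 genes as significant, 823 up and 814 down in EKO, all with an adjusted p under 0.05 and a log2 change of at least 1 in either direction. Of these, 1619 were also tested in edgeR, every one with the same sign, and 1587 had non-overlapping groups, against 42.8% of all genes tested. The calls were selected on the same counts, so neither number is separate evidence for them. The genes with the largest differences among them were chosen after the values were seen. Higher genes included the collagenase Mmp13 (25.2 ± 17.9 against 1.61 ± 1.12 CPM) and osteopontin (Spp1, 345 ± 366 against 30.6 ± 26.2 CPM). Single libraries weighed on these: without EKO replicate 2 Mmp13 was 9.39-fold higher rather than 15.7-fold and Spp1 4.35-fold rather than 11.3-fold, and without WT replicate 3 Spp1 was 21.9-fold higher. Lower genes included adipsin (Cfd, 131 ± 117 against 1866 ± 2066 CPM), resistin (Retn, 45.0 ± 27.7 against 333 ± 213 CPM) and Cyp2e1 (29.3 ± 28.4 against 777 ± 1020 CPM). Without WT replicate 2, which held the most of each, they were 5.12-fold, 4.72-fold and 6.50-fold lower rather than 14.2-fold, 7.40-fold and 26.5-fold. Without EKO replicate 1, Cfd was 25.4-fold and Cyp2e1 51.0-fold lower. Genes the authors' deposited table marks as up were enriched for 53 gene ontology terms, among them inflammatory response (53 of 271 genes, 13.8 expected) and neutrophil chemotaxis (18 of 42, 2.14 expected). Genes marked as down in the authors' deposited table were enriched for 24 terms, among them brown fat cell differentiation (13 of 35, 1.76 expected) and triglyceride biosynthetic process (9 of 16, 0.81 expected). The hypergeometric test behind these counts treats genes as independent and takes no account of correlation between them. Its genes match DESeq2 calls, and DESeq2 without a fold threshold gave 72 false among 193 calls in the simulation. That simulation changed 200 genes, while 5264 genes had an unadjusted edgeR p under 0.05 in the data. A false share depends on how many genes change, so that of the simulation does not carry over to the authors' calls. Camera over 2157 terms called 37 higher and 30 lower at the preset correlation, led by fatty acid beta-oxidation (40 genes, median log2 -0.62), and 0 with an estimated correlation (adjusted p = 0.910 for that term).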

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

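The count of genes passing edgeR stayed at 0 under every other scaling, filter and stricter threshold and under the newer and robust edgeR fits, which, like an adjusted p of 0.10, were added after the data were seen. DESeq2 called 3392 genes (1757 higher, 1635 lower), limma-voom with quality weights 4101 (2387 and 1714), and edgeR at an adjusted p of 0.10 called 3560 (2150 and 1410), by the looser threshold itself. For the different tests the cause was not tested. Leaving out each library in turn gave 0 to 443 genes (0 to 323 higher, 0 to 120 lower), with every call coming from the set without WT replicate 2, and 3332 to 4903 genes at an unadjusted p under 0.05, lowest without EKO replicate 2. No pairing by replicate number was seen, as deviations of same-numbered libraries correlated at 0.27, -0.31 and -0.35, and not every library correlated best with its own number. With deviations taken from the mean of so few libraries per genotype, this check cannot exclude a pairing. With the replicate block edgeR called 0 genes, 4258 at an unadjusted p under 0.05, and camera 24 lists. Eepd1 kept its direction in all settings, at -1.26 in DESeq2 and -1.05 with quality weights, where it passed, and at -1.57 to -0.90 without single libraries, where it did not. Of 69 other tested genes named in the text, 65 passed in DESeq2, 62 with quality weights and 22 without WT replicate 2. Many of them were named for a small p or a large change in these data, so these counts do not describe genes at large. Prm1 ranged from -9.74 (without EKO replicate 3) to 0.77 (without WT replicate 2). Camera called 23 lists, and 22 to 26 without single libraries, with 22 of the 23 called in every such set. It called 9 with a median log2 of at least 1 in size and 0 with an estimated correlation. Fry called 4, each at an adjusted p of 0.0489. Of these, insulin signalling, endoplasmic reticulum stress and red cell transcripts are among the 23, and DNA damage response is not. The adipocyte identity, lipolysis, lysosome and both macrophage lists had a fry adjusted p of 0.117. The 67 ontology terms became 314 with no count filter, 0 with an estimated correlation, 0 with fry and 64 to 115 without single libraries (103 without WT replicate 1, 115 without WT replicate 3). The list test already uses voom values, so limma-voom gave it no further value. At 17215072 to 18330206 counts, the spread between libraries rather than depth set the standard errors of abundant genes, while Ucp1 was limited by its counts.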

Other observations

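In lists that were not called, the genes named here had non-overlapping groups, and none passed over all genes tested in edgeR. The rule took them from the members with the smallest p of each list, so the separation follows in part from that choice. Of all genes tested, 42.8% had non-overlapping groups. Peroxiredoxin Prdx1 averaged 2301 ± 1692 CPM in EKO and 385 ± 37.5 in WT (SD, n = 3), and Srxn1, which repairs oxidised peroxiredoxins, was 6.19-fold higher (3.48-fold for Prdx1 and 3.57-fold for Srxn1 without EKO replicate 2), while the antioxidant list as a whole had 10 genes higher and 9 lower. In glycolysis, Slc2a1, the glucose transporter, and Pkm, the pyruvate kinase, were 3.42-fold and 2.89-fold higher, in a list with 10 genes higher and 9 lower, of which 7 higher and 3 lower passed when adjusted over the list alone, against 0 over all genes. The chemokine genes Ccl3 and Ccl4 were 5.26-fold and 5.94-fold higher and Cxcl9 was 2.40-fold lower, in a cytokine list with 20 genes higher and 7 lower, of which 3 higher and 0 lower passed when adjusted over the list alone. Among genes of alternative macrophage activation, the lectin genes Mgl2 and Cd209a were 3.17-fold and 2.33-fold lower and the folate receptor Folr2 2.43-fold higher, in a list with 10 genes higher and 7 lower. The clock genes Npas2 and Nr1d1 differed in opposite directions, 4.42-fold higher and 1.74-fold lower, in a list with 5 genes higher and 12 lower. The edgeR adjusted p of these genes lay between 0.0628 and 0.0819.

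In what follows, the tests of WT replicate 2, of the adipocyte share and of Eepd1 were chosen after the results were seen, and the tests of scaling and of other splits before, although the counts at an unadjusted p and of ontology terms were themselves added after.

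Leaving out WT replicate 2 took edgeR from 0 to 443 genes. In 77.3% of the 441 of these genes that were also tested with 6 libraries, WT replicate 2 was the WT library furthest from EKO. These genes were selected by leaving that library out, so the same share was taken for WT replicates 1 and 3 over as many genes with the lowest p without each, and came to 21.5% and 2.49%. A WT replicate 2 further from EKO along the same difference may therefore account for part of the lost calls. The 118 genes lower in EKO among the 441 lay at a median log2 of 0.0189 (median absolute deviation 0.28) from WT replicates 1 and 3. The 323 higher ones lay at -1.18 (0.45), so the distance was seen in the higher genes. Testis RNA in that library, which held Prm1 at 412 CPM, would dilute the fat transcripts of both sets alike. These medians therefore argue only against dilution alone as the cause of the distance in the higher genes. The mean log2 CPM of the adipocyte list was also not lower in WT replicate 2 (10.1) than in WT replicates 1 and 3 (9.98 and 9.61). Neither the medians nor the list mean can exclude dilution combined with a WT replicate 2 further from EKO. Such a distance would raise the genes lower in EKO, and dilution could offset that rise. Dilution as part of the cause therefore stays open.

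Lower adipocyte and higher macrophage transcripts in EKO may reflect a change in tissue composition with genotype. A lower share of adipocytes alone would raise every other cell type alike, but the macrophage median lay 2.24 log2 units above the endothelial one, against 0.46 for the spread of their members. The adipocyte median was -1.44 (median absolute deviation 0.60) under the alternative to TMM that brought it nearest to 0, and -1.40 with TMM. The alternative scalings shifted the median over all genes by only -0.046 to -0.0995 from TMM. The choice among them therefore does not account for the lower adipocyte transcripts. A scaling fault shared by all of them was not tested. Testis RNA in WT replicate 2 as the whole cause of the higher macrophage transcripts is argued against by a macrophage median of 1.01 (0.33) without that library, against 1.29 with it. A gain of macrophages with genotype, or a change in the transcripts each cell makes, stays open, and no test here separates them.

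Eepd1 counts in EKO remained at 42.6% of WT. A swapped label of 1 library would account for the counts of that library alone, and each of the 3 EKO libraries held Eepd1, the lowest at 47.7 CPM. Eepd1 alone leaves open whether any single label is swapped. The gap of 40.3 CPM between the highest EKO and the lowest WT library is smaller than the SD of either group (52.9 and 56.1 CPM). Exchanging the labels of 1 EKO and 1 WT library gave at most 738 genes at an unadjusted edgeR p under 0.05, against 5264 as labelled. These counts argue against such an exchange, provided that the genotypes differ in many genes. Relative to the mean of the adipocyte list, log2 Eepd1 was not lower but 0.33 higher in EKO (pooled SD 0.16, two-sided exact permutation p = 0.2, smallest possible 0.1, n = 3). If Eepd1 followed the adipocyte transcripts, a difference under the pooled SD was predicted, and if not, a ratio lower in every EKO library. Neither was met, so whether the lower Eepd1 counts follow the lower adipocyte transcripts stays open. Such following cannot be told apart from transcripts still made by the targeted allele, because the counts cover the whole gene and the groups hold 3 libraries each.

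The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. As many genes as in the real split were called by edgeR in 10 of the 10 splits (0 genes, highest other 0), and 1 of the 10, the real one, gave 5264 genes at an unadjusted p under 0.05 (highest other 738). The real split was also 1 of the 10 for DESeq2, with 3392 genes (highest other 598). Camera called at least 23 lists in 3 of the 10 splits (highest other 23) and at least 67 ontology terms in 5 of the 10 (highest other 134, with EKO replicates 1 and 2 and WT replicate 2 on one side), so list and term calls at the preset correlation also arise in regrouped libraries. Each of the 9 other splits keeps 2 libraries of a genotype together on either side, so part of any genotype difference remains in them.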
